A study of Homo sapiens with 12 samples.

How the data were processed

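RNA from HepG2 cells was measured on 12 Affymetrix HuGene 1.0 ST arrays in 4 groups of 3, namely total RNA, T7 RIP, ELAVL1 RIP and PABPC1 RIP. Per the labels' protocols, antibody-coated magnetic beads were incubated with cell lysate overnight and the RNA was extracted with phenol and chloroform. Per the series' design text, replicates are separate RIP runs. Array signals were made with PLIER, per the submitters' processing notes, and its version is not given in the sources used here. The deposited values are on the log2 scale with a floor of 4 on every array. Their medians differ between groups, and the normalization between arrays is not given in the sources used here. Per the labels, each group also has a region list in 2 versions, with 1 region per transcript cluster. The deposited lists hold a signal per region, a score that equals a fixed scale times 1 minus p over 0.05, and a p-value and q-value. The second version of each list holds the same regions with the deposited p-value as -log10. The reference of the deposited signal in 3 of the lists, whose values start at 2, is not given in the sources used here.

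The value table holds 28869 transcript clusters. Of these 19310 carry 1 gene symbol, 1752 carry several and 7807 are not listed in the table of probes and genes, which names 18377 distinct genes. Kept for testing were the 18749 clusters above the array median on at least 3 arrays. A single limma model with the 4 groups was fitted to all 12 arrays (limma 3.58.1, R 4.3.3, 8 residual and 75.75 prior degrees of freedom), with Benjamini-Hochberg adjustment and a threshold of 0.05. The median SE of a log2 change was 0.44. Since group medians differ, gene and list values in the text come from the fit with each array centred on its median, while the leading design used the values as deposited. Both counts are given.

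Gene lists were tested with camera (preset correlation 0.01) over 14035 named genes, 1 cluster per gene. None of the calls held when the correlation was estimated per list. The self-contained test fry was run beside it, which does not compare a list with other genes. The mitochondrially encoded list matched no cluster and was not tested. Genes to name were fixed by a rule, namely both antibody targets, the 8 largest and 5 smallest changes with groups that do not overlap, up to 2 members each way per list and 10 genes over both controls. The rule gave 369 pairs of a gene and a comparison. The text names a part of them, chosen after their values were seen. Of the 369, 9 changed sign and 30 lost their call on centred or quantile-normalized arrays. As deposited, 30 lost it with the date as a random block, and 29 lost it without at least 1 array, with 69 losses over all left-out arrays. For each list and comparison 10000 random lists were matched on the mean level in the second group, a step chosen after the values were seen.

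Alternatives fixed beforehand were quantile normalization, median centring, no filter and a filter at the 75th percentile, limma with trend and robust options, only the 6 arrays of a comparison, a change of at least 1 log2 unit, the replicate number as a block, the date as a block, and each array left out in turn. Alternatives with another pseudocount did not apply because the table is already on the log2 scale. Whether replicate numbers pair the arrays was checked from the correlation of deviations from group means. Arrays of the same number correlated between -0.0527 and 0.396 (median 0.134), and 12 of 18 pairs were over 0.1. All 3 pairs passed 0.1 in ELAVL1 RIP with T7 RIP and in PABPC1 RIP with total RNA only. The arrays fall into 4 date batches. ELAVL1 RIP and PABPC1 RIP share 1 date, and T7 RIP replicate 1 shares the date of total RNA.

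The fits were tested on simulated data with 200 of 18749 clusters changed. In the ELAVL1 RIP over T7 RIP simulation 60% of changes of 2 log2 units and 0% of changes of 1 were recovered, and in PABPC1 RIP over T7 RIP 59% and 0%. As deposited the real fits called 8047 to 15859 clusters, which makes the adjusted threshold less strict than in the simulation. The simulated shares are therefore not those of the real fits. Region lists were compared with bedtools 2.31.1 at a reciprocal overlap of 0.5, and log2 signals were called equal within 0.001. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for the rest.

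In the closing tests of list medians, an explanation was counted as met or excluded only when the whole bootstrap interval lay past a written bound. The bootstrap drew genes, so its intervals measure the spread between the members of a list and not that between arrays. The test of matched lists was decided by the share of 10000 random lists, those of region records by a count and an area under the curve, and those of other splits by the share of splits, without an interval. The bounds for the 3 lists used on the arrays labelled PABPC1 RIP and for the matched lists were written before those tests were run, and those for scaling, the secreted class as the whole cause, date and region records after the values were seen. A looser rule, by which the median alone had to pass, was tried after the values were seen and dropped. It would have decided 3 tests on the arrays labelled PABPC1 RIP, which are given as undecided.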

Results

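RNA bound to RNA-binding proteins was measured in HepG2, a human liver cancer cell line that keeps many hepatocyte features. In RNA immunoprecipitation followed by array hybridization (RIP-chip), an antibody pulls a protein out of a cell lysate and the RNA that comes with it is measured on an array. The 12 arrays formed 4 groups of 3: total RNA, a RIP with an antibody against the T7 tag that has no target in these cells (T7 RIP), a RIP of ELAVL1 and a RIP of PABPC1. ELAVL1 (HuR) binds U-rich and AU-rich stretches of mRNAs, and PABPC1 is the main cytoplasmic protein bound to poly(A) tails. The number of arrays, 3 per group, limits the precision of every value. The array medians differed between groups. They lay between 5.90 and 6.04 on the log2 scale for total RNA, 7.13 and 7.50 for T7 RIP, 7.21 and 7.33 for ELAVL1 RIP, and 8.17 and 8.44 for PABPC1 RIP. Changes of single genes and of gene lists are therefore given relative to the array medians, as log2 change ± SE from limma with n = 3 arrays per group, and the shift of the medians is given once for each comparison. The words rose and fell refer to these relative changes at an adjusted p under 0.05. Of the 78 largest changes chosen by rule over the 6 comparisons, 50 had their lower group under the highest lower quartile of that group's arrays. Background and the floor of 4 bear on the size of such changes, which are not measured ratios.

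The comparison of ELAVL1 RIP with T7 RIP asked which RNAs came down with ELAVL1 more than with an antibody that has no target. The mRNA of ELAVL1 itself rose by 2.76 ± 0.45 (adjusted p = 9.17e-06), from a mean log2 signal of 9.16 ± 0.82 (SD, n = 3) to 11.85 ± 0.55. Its transcript cluster spans positions 8023458 to 8509925 of chromosome 19 (hg19, minus strand). The largest rise among genes whose groups did not overlap was that of KCNMA1, the pore-forming subunit of a calcium-activated potassium channel, at 5.23 ± 0.43 (chromosome 10, 78629361 to 79398353), from a T7 RIP mean of 5.96 that lay within the lower quartiles of those arrays (5.68 to 6.22). It was followed by the homeobox gene CDX2 at 5.06 ± 0.41, the neural transcription factor SOX1 at 4.91 ± 0.46 and the homeobox gene NKX6-2 at 4.83 ± 0.44. CDX2 and NKX6-2 did not pass in ELAVL1 RIP over total RNA (0.46, adjusted p = 0.374, and 0.76, adjusted p = 0.147) and were low in T7 RIP over total RNA (-4.60 and -4.07), so their rise here goes with a low T7 RIP value. KCNMA1 and SOX1 passed over both controls, and as deposited their means were 11.12 and 10.53 with ELAVL1 against 11.03 and 10.85 on the arrays labelled PABPC1 RIP. Among the largest falls were those of GAB3, an adaptor of receptor signalling (-5.95 ± 0.40), the axonemal dynein DNAH11 (-5.23 ± 0.41) and HP, the plasma protein haptoglobin (-4.43 ± 0.41). The ELAVL1 RIP means of GAB3 and DNAH11, 5.84 and 5.48, lay under the lower quartiles of those arrays, and HP was 2.80 higher in T7 RIP than in total RNA. PABPC1 mRNA did not pass the test (-0.17 ± 0.41, adjusted p = 0.773).

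Among the lists fixed beforehand, mRNAs reported as ELAVL1 targets had a median of 0.53, with 11 of 32 members rising, 2 falling and 19 not passing (11 and 2 adjusted over the list alone). BCL2, which blocks apoptosis, rose by 2.61 ± 0.45. The camera test of this list gave an adjusted p of 0.0323, and adjusted p = 0.582 with an estimated correlation. Proteasome subunits had the lowest median, -1.60, with 1 of 35 rising, 24 falling and 10 not passing (3 and 25 adjusted over the list alone). PSMD2 and PSMD8, of the regulatory particle, changed by -4.02 ± 0.42 and -3.77 ± 0.48, and PSMD5, a chaperone of its assembly, was the member that rose. The list gave an adjusted p of 7e-07 with the preset correlation and adjusted p = 0.582 with an estimated correlation. In oxidative phosphorylation, 5 of 83 genes rose, 48 fell and 30 did not pass (5 and 52 adjusted over the list alone), with a median of -1.10. The complex I subunits NDUFS3 and NDUFA8 changed by -3.25 ± 0.48 and -3.06 ± 0.43. That list gave an adjusted p of 4.46e-06, and adjusted p = 0.663 with an estimated correlation.

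Liver secreted proteins had a median of -1.32, with 0 of 33 rising, 21 falling and 12 not passing (0 and 21 adjusted over the list alone). The lipid carrier APOE changed by -3.41 ± 0.42. Their adjusted p was 6.65e-07, and adjusted p = 0.663 with an estimated correlation. Cytosolic ribosomal proteins had a median of -0.78, with 1 of 66 rising, 30 falling and 35 not passing (1 and 31 adjusted over the list alone), and RPS23 changed by -2.73 ± 0.42. Here the adjusted p was 0.000215, and adjusted p = 0.685 with an estimated correlation. Of 18 cholesterol synthesis genes 1 rose, 10 fell and 7 did not pass, the same counts adjusted over the list alone, at a median of -1.27. DHCR7, the last enzyme of the pathway, changed by -3.57 ± 0.47. The list gave an adjusted p of 0.00231, and adjusted p = 0.663 with an estimated correlation. Histones (-0.67, 4 of 47 rising, 16 falling) gave an adjusted p of 0.0301, and adjusted p = 0.741 with an estimated correlation. Without T7 RIP replicate 1 their adjusted p was 0.732. The 4 erythroid markers (median 2.10, 3 rising) gave an adjusted p of 0.0323, and adjusted p = 0.663 with an estimated correlation. Without T7 RIP replicate 1 it was 0.0907, and with no filter 0.0824. Random lists matched on the T7 RIP level, which itself enters the change, already had medians of -0.56 for proteasome subunits, -0.42 for oxidative phosphorylation, -0.74 for liver secreted proteins, -0.75 for ribosomal proteins, -0.53 for cholesterol synthesis, -0.13 for histones, -0.26 for ELAVL1 targets and 0.69 for erythroid markers. Of 10000 lists 4393 were as low as the ribosomal proteins, so this list was not low for its level. As low as the liver, cholesterol and histone lists were 140, 258 and 74, and 1 of 10000 each was as low as the proteasome and oxidative phosphorylation lists. As high as the ELAVL1 targets were 32, and as high as the erythroid markers 191.

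The other lists did not pass in this comparison with all arrays. They were the AU-rich early response mRNAs (median -0.37, adjusted p = 0.317), translation factors (-0.71, 0.352), small nucleolar and related RNAs (-0.07, 0.665), long noncoding RNAs (-0.59, 0.563), ZNF genes (0.28, 0.0995), cell cycle genes (-0.29, 0.0653) and lymphoid markers (-0.67, 0.403). Without T7 RIP replicate 1 the small nucleolar and related RNAs passed in the other direction (0.68, adjusted p = 0.0202). Cell cycle genes passed without T7 RIP replicate 2 (adjusted p = 0.0207) or replicate 3 (0.0168), and with no filter (0.0212). For RNA-binding proteins the median was 0.15 while the mean was -0.17 and the test pointed down (adjusted p = 0.601), and matched lists had a median of -0.81. Of 10000 matched lists 0 had a median as high. No mitochondrially encoded transcript on the fixed list was found on the array by symbol.

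As deposited, limma called 3230 transcript clusters higher and 4817 lower of 18749 tested, and the medians differed by -0.07. With every array centred on its median the counts were 3406 and 4390, and after quantile normalization 3685 and 3671. The array dates of ELAVL1 RIP and T7 RIP do not overlap, so date and antibody cannot be separated here. With the date as a random block 1825 were higher and 2673 lower.

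**Figure D1:**
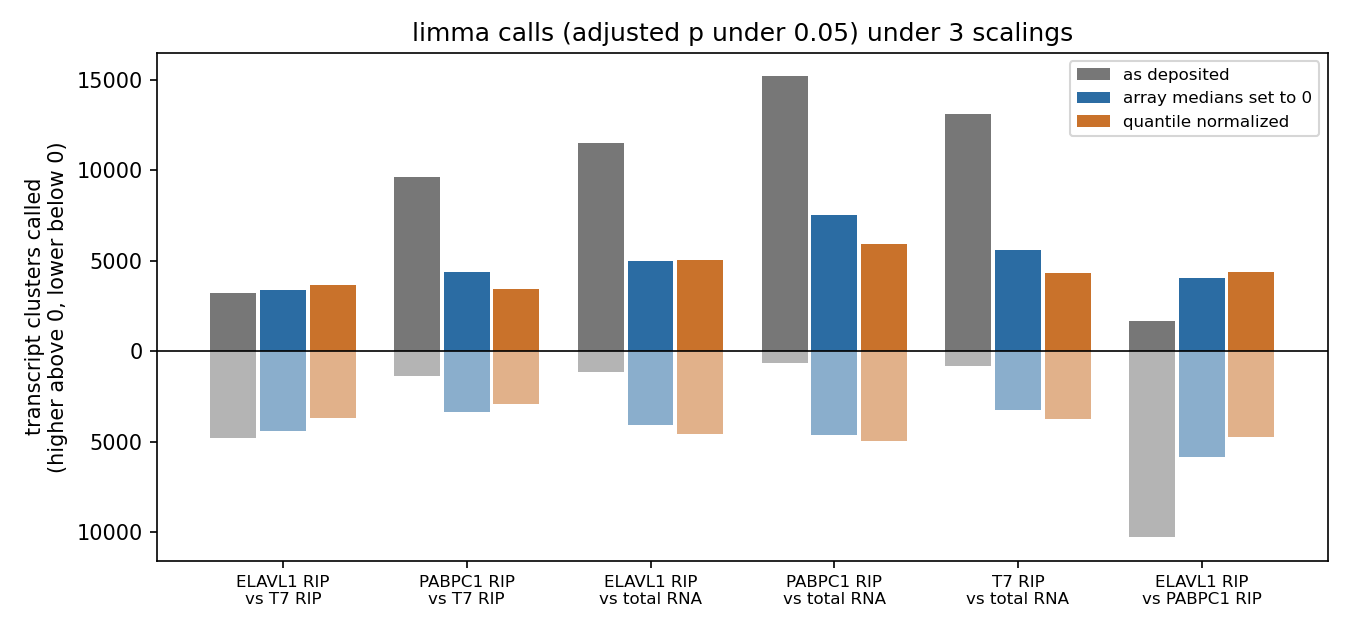
Transcript clusters called by limma (vertical axis, number of clusters, higher above 0 and lower below 0) in the 6 comparisons, with the values as deposited, with array medians set to 0 and after quantile normalization. In PABPC1 RIP over T7 RIP the higher calls go from 9644 as deposited to 4386 with medians set to 0.

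The arrays labelled PABPC1 RIP were compared with T7 RIP to find RNAs that came down with PABPC1. Whether these arrays hold HepG2 RNA is not settled, as described below, so changes on them cannot be read as PABPC1 association. CGA, the common alpha subunit of the glycoprotein hormones, rose by 6.93 ± 0.43 (chromosome 6, 87795217 to 87804850, hg19). ANXA1, a phospholipid-binding annexin, rose by 6.84 ± 0.42, the protease inhibitor SLPI by 6.06 ± 0.43, the hyaluronan receptor CD44 by 6.06 ± 0.42 and the cytokine IL6 by 5.66 ± 0.42 (chromosome 7, 22765504 to 22771620). The T7 RIP means of CGA and ANXA1, 4.94 and 4.77, were near the floor, so their changes have no exact size. Genes of the hepatocyte program were among the lowest. The plasma protein ITIH2 changed by -8.30 ± 0.48, alpha-fetoprotein (AFP) by -7.67 ± 0.44, the proteoglycan GPC3 by -7.81 ± 0.43 and the apolipoprotein APOA2 by -7.66 ± 0.42. Their means on these arrays, 5.40, 6.51, 6.06 and 6.63, lay under or near the lower quartiles (6.46 to 6.61), so background bears on the size of these changes too. The mRNA of PABPC1 did not pass (-0.53 ± 0.41, adjusted p = 0.317), and its mean was 13.71 ± 0.09 (SD, n = 3) against 13.29 ± 0.15. That of ELAVL1 passed as deposited but not relative to the medians (0.78 ± 0.45, adjusted p = 0.168).

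Of 33 liver secreted proteins 0 rose, 31 fell and 2 did not pass (0 and 31 adjusted over the list alone), at a median of -5.72. The list gave an adjusted p of 9.87e-71, and adjusted p = 0.0896 with an estimated correlation. Beside this liver median of -5.72, oxidative phosphorylation genes had a median of 0.75, with 37 of 83 rising, 3 falling and 43 not passing (37 and 3 adjusted over the list alone). COX7A2 and NDUFB11 rose by 3.14 ± 0.47 and 3.12 ± 0.49. Their adjusted p was 0.00137, and adjusted p = 0.685 with an estimated correlation. On the same arrays small nucleolar and related RNAs had a median of -1.27, with 2 of 78 rising, 36 falling and 40 not passing (2 and 37 adjusted over the list alone). SNORD116-14 and SNORD116-20, of an imprinted snoRNA cluster, changed by -7.35 ± 0.53 and -6.51 ± 0.54, to means of 4.19 and 5.14 near the floor, which sets the size of these changes, and the T7 RIP SD of SNORD116-14 was 1.51 (n = 3). The list gave an adjusted p of 4.89e-13, and adjusted p = 0.663 with an estimated correlation. Without T7 RIP replicate 1 its median was -0.67 (adjusted p = 5.42e-05), and as deposited 10 members were higher and 21 lower. RNA-binding proteins had a median of -0.73, with 1 of 41 rising and 13 falling (1 and 10 adjusted over the list alone), and IGF2BP2 changed by -4.04 ± 0.41. Here the adjusted p was 0.00625, and adjusted p = 0.685 with an estimated correlation, while random lists of the same T7 RIP level had a median of -0.88, so the RNA-binding proteins were not low for their level. As deposited 7 RNA-binding proteins were higher and 3 lower, 159 ZNF genes and 21, and 16 histones and 6. Proteasome subunits (median 0.48, 12 of 35 rising, 0 falling, adjusted p = 0.144) passed with all transcript clusters (0.0156) and with no filter (0.0421). The ELAVL1 target list did not pass (median 0.11, adjusted p = 0.144), although IL6 and the chemokine CXCL8 (4.70 ± 0.46) are on it. Nor did histones (-0.63, adjusted p = 0.141), ZNF genes (-0.34, 0.0837) or lymphoid markers (-1.56, 0.0629) pass. Histones passed without T7 RIP replicate 3 (adjusted p = 0.00512) and with the replicate block (0.0419). ZNF genes passed without T7 RIP replicate 2 (0.0294) or PABPC1 RIP replicate 1 (0.0474), and lymphoid markers without T7 RIP replicate 1 (0.0181) or PABPC1 RIP replicate 2 (0.0437), and with the replicate block (0.0315).

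The values as deposited gave 9644 transcript clusters higher and 1349 lower, with the medians 0.95 apart. Centred arrays gave 4386 higher and 3330 lower, and quantile normalization 3421 and 2911. These groups share no array date either, and with the date as a random block 887 were lower as deposited.

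**Figure D2:**
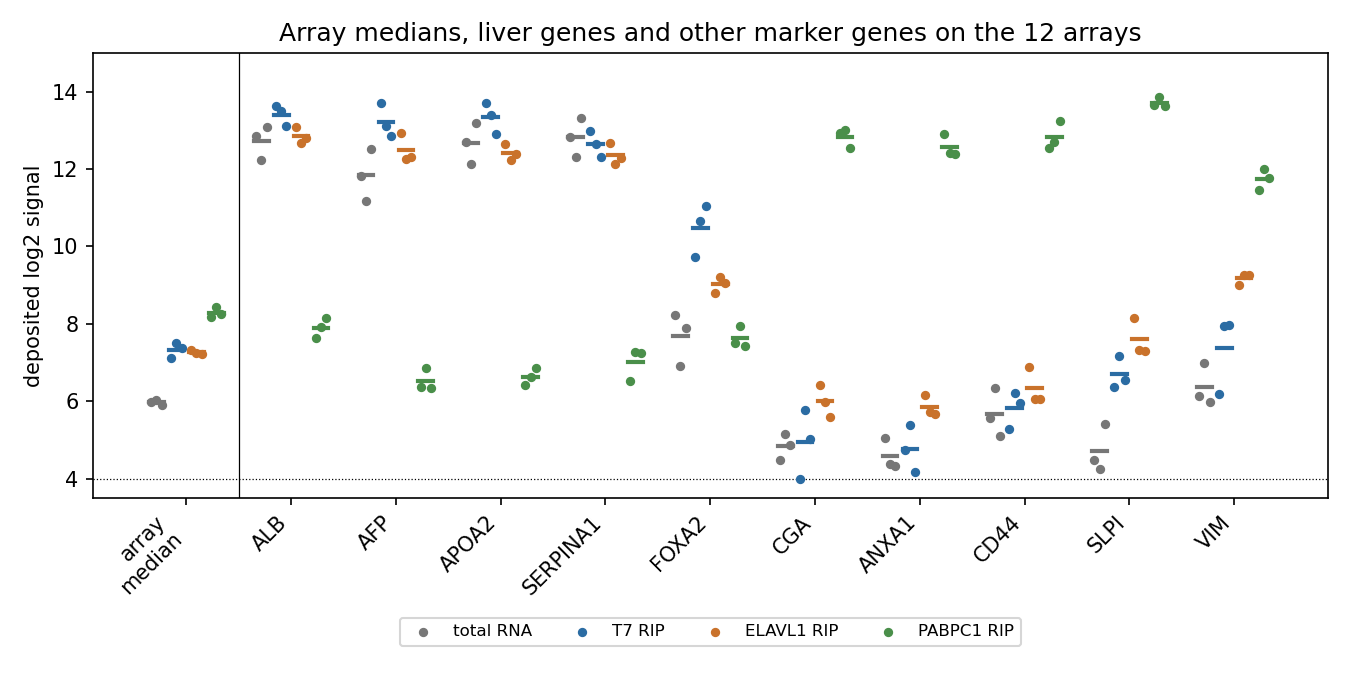
Deposited log2 signal (vertical axis) of each array for the array median and for 10 marker genes, with 1 point per array, a bar for the mean of the 3 arrays of a group and a dotted line at the floor of 4. AFP has a mean of 6.51 on the PABPC1 RIP arrays against 13.23 on the T7 RIP arrays, and CGA 12.83 against 4.94.

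ELAVL1 RIP and the arrays labelled PABPC1 RIP were hybridized on 1 date and were compared directly. Lysozyme (LYZ) was higher with ELAVL1 by 8.01 ± 0.45, AFP by 7.01 ± 0.44 and APOA2 by 6.82 ± 0.42. LDHB, a lactate dehydrogenase subunit, changed by -6.02 ± 0.42 and IL6 by -6.01 ± 0.42. ELAVL1 mRNA was 1.98 ± 0.45 higher relative to the medians (adjusted p = 0.000373) and did not pass as deposited (0.96, adjusted p = 0.0586, and 0.0244 without ELAVL1 RIP replicate 1). Of 33 liver secreted proteins 30 rose and 2 fell, the same counts adjusted over the list alone, at a median of 4.53. The adjusted p was 7.65e-29, and adjusted p = 0.389 with an estimated correlation. Beside that liver value, oxidative phosphorylation genes had a median of -1.97, with 2 of 83 rising and 67 falling (2 and 68 adjusted over the list alone), and COX7B changed by -4.49 ± 0.40. They gave an adjusted p of 1.27e-11, and adjusted p = 0.582 with an estimated correlation. Proteasome subunits had a median of -2.06, with 0 of 35 rising and 28 falling (1 and 28 adjusted over the list alone), and PSMD8 changed by -4.31 ± 0.48. Here the adjusted p was 1.01e-07, and adjusted p = 0.582 with an estimated correlation. Small nucleolar and related RNAs had a median of 1.27, with 37 of 78 rising and 4 falling. Their adjusted p was 5.59e-09, and adjusted p = 0.663 with an estimated correlation. ZNF genes (0.49, 124 of 365 rising and 82 falling adjusted over the list alone) and ribosomal proteins (-0.67, 3 of 66 rising, 31 falling) gave adjusted p values of 0.00368 and 0.0242. These were adjusted p = 0.582 and 0.741 with an estimated correlation. RNA-binding proteins (0.63, adjusted p = 0.0551) passed without ELAVL1 RIP replicate 1 (0.0251) or PABPC1 RIP replicate 1 (0.0315). Cell cycle genes (-0.91, adjusted p = 0.126) and cholesterol synthesis genes (-0.71, 0.115) passed with no filter (0.0287 for both). The ELAVL1 target list did not pass between the ELAVL1 and PABPC1 arrays, with 10 of 32 rising, 9 falling and 13 not passing (median 0.53, mean 0.16, adjusted p = 0.679). For this list random lists matched on the PABPC1 RIP level had a median of -0.82, and 2 of 10000 were as high. As high as the RNA-binding proteins were 0 of 10000. As deposited 2 ELAVL1 target mRNAs were higher and 15 lower, 25 and 18 of the small nucleolar and related RNAs, 64 and 164 of the ZNF genes and 4 and 17 of the RNA-binding proteins, so the balance turned with the scaling in all of these lists but the small nucleolar RNAs. Random lists matched on the PABPC1 RIP level had medians of 1.14 for the small nucleolar and related RNAs and 0.42 for ZNF genes, and 2171 and 1886 of 10000 were as high, so neither list was high for its level. They had -1.04 for oxidative phosphorylation and -1.15 for proteasome subunits, with 1 and 29 of 10000 as low. For liver secreted proteins they had 1.57, with 0 as high. For ribosomal proteins they had -1.26, with 193 as high, so the ribosomal proteins were not low for their level. As deposited, 1685 transcript clusters were higher with ELAVL1 and 10287 lower, with the medians -1.02 apart. The counts were 4032 and 5859 on centred arrays and 4383 and 4736 after quantile normalization.

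**Figure D3:**
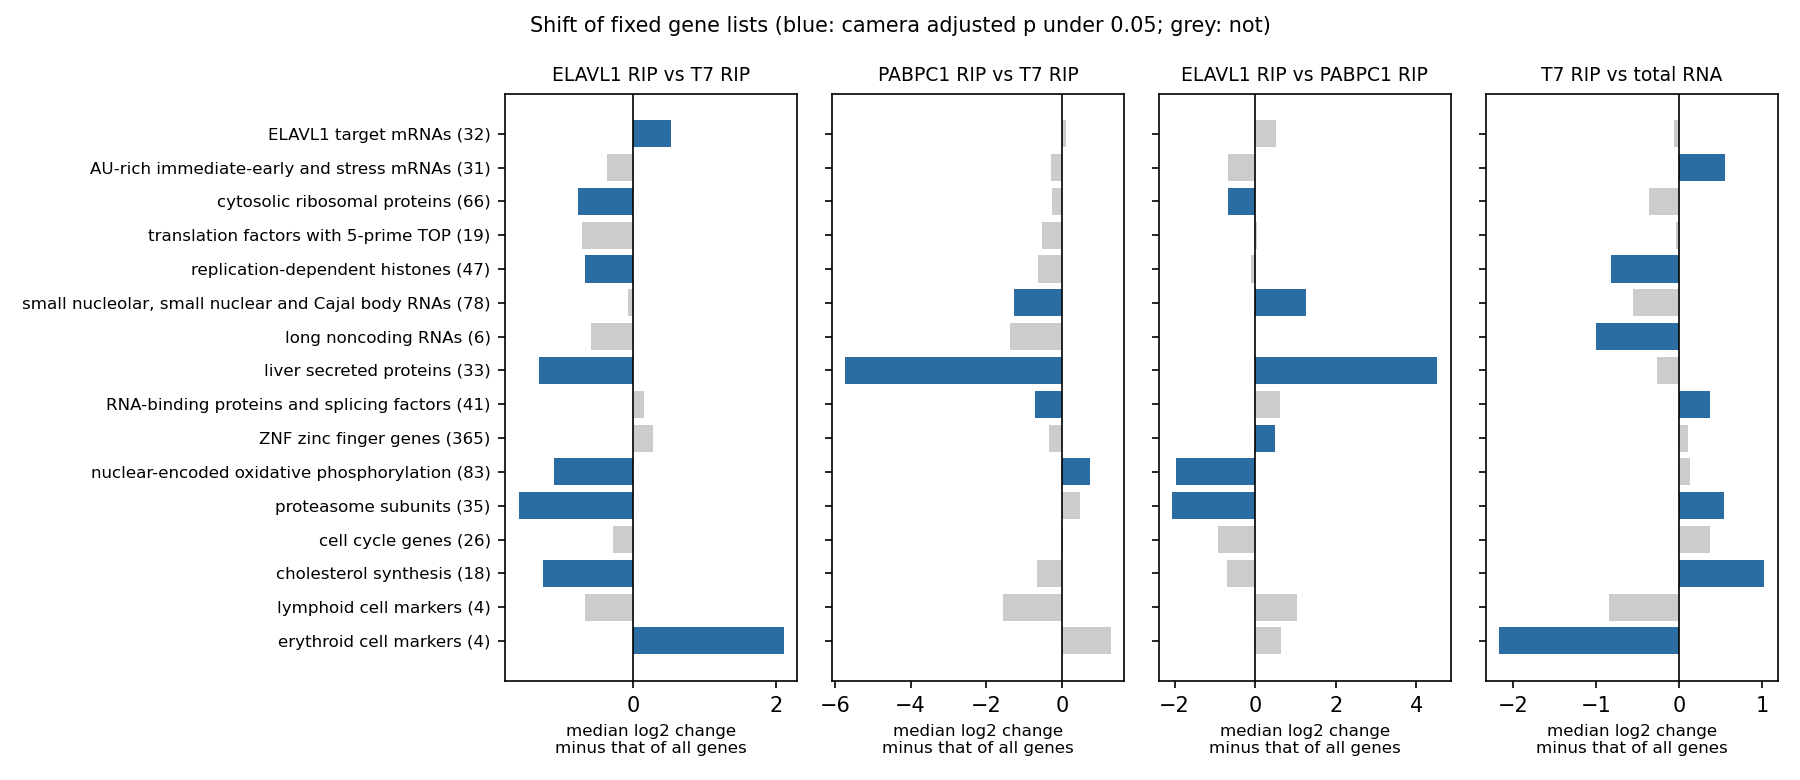
Median log2 change of each fixed gene list minus that of all genes (horizontal axis) in 4 comparisons, with the number of tested members in parentheses and blue bars for camera adjusted p under 0.05. The liver secreted proteins lie at -5.72 in PABPC1 RIP over T7 RIP and at 4.53 in ELAVL1 RIP over PABPC1 RIP. None of the blue bars holds with an estimated correlation.

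T7 RIP against total RNA gave the background of the RIP procedure. The muscle membrane protein SGCB rose by 5.11 ± 0.48 and the mitochondrial enzyme ALDH6A1 by 4.55 ± 0.47. FAM83B changed by -6.41 ± 0.46 and ST3GAL5, which makes the ganglioside GM3, by -5.70 ± 0.44. Of 18 cholesterol synthesis genes 15 rose and 2 fell, the same counts adjusted over the list alone, at a median of 1.02, with MVD and PMVK at 2.82 ± 0.50 and 2.65 ± 0.43. The adjusted p was 0.0154, and adjusted p = 0.685 with an estimated correlation. Without total RNA replicate 2 it was 0.0552. RNA-binding proteins had a median of 0.38, with 20 of 41 rising and 0 falling, also adjusted over the list alone, and the RNA helicase DHX9 rose by 2.92 ± 0.50. This list gave an adjusted p of 0.0172, and adjusted p = 0.741 with an estimated correlation. After quantile normalization the cholesterol and RNA-binding lists both gave 0.0521. Calls of 5 further lists depended on single arrays. AU-rich mRNAs (0.55, adjusted p = 0.0445, and adjusted p = 0.741 with an estimated correlation) gave 0.159 without T7 RIP replicate 2 and 0.0727 without total RNA replicate 3. Histones (-0.82, adjusted p = 0.0154, and adjusted p = 0.741 with an estimated correlation) gave 0.322 without T7 RIP replicate 3 and 0.0657 without total RNA replicate 3. Proteasome subunits (0.54, adjusted p = 0.0484, and adjusted p = 0.741 with an estimated correlation) gave 0.181 without T7 RIP replicate 1 and 0.131 without total RNA replicate 2. Long noncoding RNAs (0 of 6 rising, 2 falling, adjusted p = 0.0478, and adjusted p = 0.582 with an estimated correlation) gave 0.0994 without T7 RIP replicate 2, 0.0697 without T7 RIP replicate 3, 0.0560 without total RNA replicate 3 and 0.126 with all transcript clusters. Erythroid markers (-2.17, adjusted p = 0.0478, and adjusted p = 0.663 with an estimated correlation) gave 0.111 without T7 RIP replicate 1, 0.0517 without total RNA replicate 1, 0.0552 without total RNA replicate 2 and 0.0618 with all transcript clusters. Small nucleolar and related RNAs (-0.56, adjusted p = 0.0572) passed without T7 RIP replicate 1 (7.2e-07), without total RNA replicate 1 (0.025) or 3 (0.0243), with no filter (0.011) and with the replicate block (0.0364). With no filter the long noncoding RNAs gave 0.0888 and the erythroid markers 0.0734, and with the replicate block the AU-rich mRNAs gave 0.0845 and the long noncoding RNAs 0.0582. As deposited 25 histones were higher and 2 lower, 49 small nucleolar and related RNAs and 1, and 2 long noncoding RNAs and 1. Random lists of the same total RNA level had medians of -0.80 for long noncoding RNAs and -0.35 for histones, with 3801 and 566 of 10000 as low. As deposited 13114 transcript clusters were higher and 840 lower, with the medians 1.36 apart. Centred arrays gave 5585 and 3263, and quantile normalization 4300 and 3759. Centring without total RNA replicate 2, an alternative chosen after seeing the data, gave 3486 and 2378.

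Against total RNA, ELAVL1 mRNA rose by 3.12 ± 0.45 in ELAVL1 RIP (adjusted p = 8.48e-07). The guanine nucleotide exchange factor IQSEC3 rose by 4.99 ± 0.43 and the cap-binding factor EIF4E by 3.56 ± 0.42. The RNA component of RNase P, RPPH1, changed by -5.65 ± 0.62. Of 32 ELAVL1 target mRNAs 16 rose and 1 fell, the same counts adjusted over the list alone, at a median of 0.99. The adjusted p was 0.0221, and adjusted p = 0.582 with an estimated correlation. For this list random lists of the same total RNA level had a median of -0.37, and 0 of 10000 were as high. This was not particular to the targets, since 0 of 10000 were also as high as the RNA-binding proteins (matched median -1.07). In T7 RIP over total RNA 2548 of 10000 were as high as the ELAVL1 targets and 0 as high as the RNA-binding proteins. Histones had a median of -1.14, with 0 of 47 rising and 21 falling, also adjusted over the list alone, and H1-2 changed by -3.18 ± 0.48 (as deposited -1.89, adjusted p = 0.000246, and 0.0912 with the date as a random block). They gave an adjusted p of 4.47e-06, and adjusted p = 0.663 with an estimated correlation. Liver secreted proteins (-1.59, adjusted p = 7e-07), ribosomal proteins (-0.98, 5.81e-05) and oxidative phosphorylation genes (-0.80, 0.00284) were also low, with adjusted p = 0.663, 0.663 and 0.727 with an estimated correlation. So were long noncoding RNAs (-1.12, adjusted p = 0.0154), with adjusted p = 0.451 with an estimated correlation and 0.134 after quantile normalization. With all transcript clusters of each gene the median of the long noncoding RNAs turned to 0.23 and the list did not pass (0.143). Calls of 3 more lists depended on single arrays. Proteasome subunits (-0.94, adjusted p = 0.0216, and adjusted p = 0.741 with an estimated correlation) gave 0.0856 without total RNA replicate 3. Small nucleolar and related RNAs (-0.70, adjusted p = 0.0301, and adjusted p = 0.828 with an estimated correlation) gave 0.207 without total RNA replicate 2, 0.0801 without ELAVL1 RIP replicate 2, 0.0671 without ELAVL1 RIP replicate 3 and 0.0976 with all transcript clusters. ZNF genes (0.43, adjusted p = 0.0498, and adjusted p = 0.663 with an estimated correlation) gave 0.0580 without total RNA replicate 1, 0.115 without total RNA replicate 3, 0.122 without ELAVL1 RIP replicate 1 and 0.0530 with the replicate block. RNA-binding proteins (0.75, adjusted p = 0.0930) passed without ELAVL1 RIP replicate 1 (0.0400), with all transcript clusters (0.0349) and with no filter (0.0208). The balance of rises and falls of 6 low lists turned with the scaling. As deposited 12 histones were higher and 5 lower, 17 ribosomal proteins and 3, 30 oxidative phosphorylation genes and 4, 11 proteasome subunits and 1, 34 small nucleolar and related RNAs and 7, and 3 long noncoding RNAs and 2. Random lists of the same total RNA level had medians of -1.28 for liver secreted proteins, -1.45 for ribosomal proteins and -1.01 for long noncoding RNAs, with 1227, 9947 and 4234 of 10000 as low, so these 3 lists were not low for their level. As deposited 11517 transcript clusters were higher and 1128 lower, with the medians 1.29 apart. ELAVL1 RIP and total RNA share no array date, and with the date as a random block 617 were lower as deposited. On centred arrays the counts were 4978 and 4070 (4091 and 3716 without total RNA replicate 2), and after quantile normalization 5049 and 4584.

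For the arrays labelled PABPC1 RIP against total RNA, SLPI rose by 6.68 ± 0.43 and the interferon-induced protein IFITM1 by 5.71 ± 0.42, while APOA2 changed by -8.36 ± 0.42 and the plasma protein AHSG by -8.20 ± 0.43. Liver secreted proteins had a median of -5.72, with 1 of 33 rising and 30 falling (1 and 31 adjusted over the list alone). The adjusted p was 1.67e-53, and adjusted p = 0.107 with an estimated correlation. Beside them 63 of 83 oxidative phosphorylation genes rose and 1 fell, the same counts adjusted over the list alone, at a median of 0.86, with NDUFS7 at 3.76 ± 0.47. That list gave an adjusted p of 0.000323, and adjusted p = 0.685 with an estimated correlation. Proteasome subunits (0.85, 29 of 35 rising, 1 falling) gave an adjusted p of 0.00453, and adjusted p = 0.685 with an estimated correlation. Small nucleolar and related RNAs (-2.19, adjusted p = 5.42e-15) and histones (-1.53, 0.00107) were low, with adjusted p = 0.604 and 0.685 with an estimated correlation. Long noncoding RNAs (-2.30, adjusted p = 0.0221) and lymphoid markers (-2.61, 0.0230) had adjusted p = 0.467 and 0.582 with an estimated correlation, and 0.11 and 0.0509 after quantile normalization. Of 32 ELAVL1 target mRNAs 19 rose, 3 fell and 10 did not pass on these arrays (median 0.33, adjusted p = 0.126, and 0.0195 with no filter). For this list random lists of the same total RNA level had a median of -0.51, and 137 of 10000 were as high. As deposited 27 histones were higher and 2 lower, 36 small nucleolar and related RNAs and 10, 3 long noncoding RNAs and 2, and 1 lymphoid marker and 0. Random lists of the same total RNA level had a median of -1.46 for the long noncoding RNAs, with 1718 of 10000 as low, and of -1.80 for liver secreted proteins, with 0 as low. AU-rich mRNAs (0.07, adjusted p = 0.251) passed with no filter (0.0421). PABPC1 mRNA was higher as deposited (2.06, adjusted p = 1.32e-05) and at -0.26 ± 0.41 relative to the medians (adjusted p = 0.595). As deposited 15199 transcript clusters were higher and 660 lower, with the medians 2.32 apart. PABPC1 RIP and total RNA share no array date, and with the date as a random block 396 were lower as deposited. Centred arrays gave 7542 and 4634 (6458 and 4162 without total RNA replicate 2), and quantile normalization 5909 and 4934.

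RNAs higher in a RIP than in both controls were counted next. KCNMA1, SOX1, ZNF280C and TNFSF15, a cytokine of the TNF family, led the ELAVL1 set, with ZNF280C at 4.79 ± 0.44 over T7 RIP and 4.03 ± 0.44 over total RNA. CGA, ANXA1, PARP6 and SLPI led the PABPC1 set, beside the liver median of -5.72 on those arrays. The total RNA means of CGA, ANXA1 and SLPI were 4.84, 4.58 and 4.72, under the lower quartiles of the total RNA arrays (4.94 to 5.15). Whether the arrays labelled PABPC1 RIP hold HepG2 RNA is not settled, so this set and its overlap cannot be read as PABPC1 association. With ELAVL1, 2823 transcript clusters were higher than in both controls as deposited, 2305 on centred arrays and 2484 after quantile normalization. Independent lists would share 1984 as deposited and 904 on centred arrays. With the date as a random block the deposited count for ELAVL1 was 1501. With PABPC1 the counts were 9077 as deposited, 3394 on centred arrays and 2467 after quantile normalization. Here independent lists would share 7818 as deposited and 1764 on centred arrays. Both comparisons behind such a count use the same RIP arrays, so their lists are not independent. Higher over T7 RIP with both proteins were 2190 as deposited, 1248 on centred arrays and 991 after quantile normalization, where independent lists would share 1661 as deposited and 797 on centred arrays. On centred arrays 334 were higher with ELAVL1 and lower with PABPC1, against 605 for independent lists. Across transcript clusters the log2 changes over T7 RIP correlated at r = 0.290, where unchanged groups simulated against the same controls gave 0.498. Genes are not independent replicates. The covariance was 0.600 against a simulated 0.105. The 3 T7 RIP arrays cannot be split, so part of the excess may come from the shared controls. The ELAVL1 and PABPC1 arrays also share a date that no T7 RIP array has, which cannot be separated here. With the date as a random block the shared set as deposited was 1037.

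The deposited region lists were compared by position (hg19). ELAVL1 RIP was listed with 5585 regions and PABPC1 RIP with 3575, and 1156 were shared where independent lists would share 692. Of the ELAVL1 regions 3698 were tested, and 1752 of these (47.4%) were called higher over T7 RIP on centred arrays and 142 lower. Among all tested clusters 3406 of 18749 were higher in that comparison. Of the PABPC1 regions 2845 were tested, 1737 (61.1%) were called higher and 72 lower, beside 4386 of 18749 higher among all tested clusters. The CGA region had a deposited signal of 433 in the PABPC1 list, IL6 of 294 there, and ELAVL1 of 14.7 in the ELAVL1 list. The list recorded under total RNA held 2941 regions and shared 193 with the ELAVL1 list and 71 with the PABPC1 list, where independent lists would share 569 and 364. Counting any overlap of 1 base, it shared 363 and 178. The list recorded under T7 RIP held 19329 regions, and its signals equal the mean of the total RNA arrays in all 19329. It shared 2462 regions with the list recorded under total RNA, 3838 with the ELAVL1 list and 2664 with the PABPC1 list, where independent lists would share 1969, 3739 and 2394.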

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

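The choices listed as alternatives were made before the data were examined, except that centring without total RNA replicate 2 was chosen after seeing the data. Alternatives with another pseudocount were not run, because the table is already on the log2 scale. Trend and robust options, no filter, the 6 arrays of a comparison alone and a change of at least 1 log2 unit left each of the 15 counts within 1.5 times. The cause of the differences below was not tested, except that a stricter filter tests fewer clusters.

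Centred on their medians, the arrays gave 4386 higher and 3330 lower in PABPC1 RIP over T7 RIP, 4978 higher and 4070 lower in ELAVL1 RIP over total RNA and 7542 higher and 4634 lower in PABPC1 RIP over total RNA. This scaling also gave 5585 higher and 3263 lower in T7 RIP over total RNA, 4032 higher and 5859 lower in ELAVL1 RIP over PABPC1 RIP and 3394 higher in PABPC1 RIP over both controls. This scaling also gave 1248 higher over T7 RIP with both proteins. Quantile normalization gave 3421 higher and 2911 lower in PABPC1 RIP over T7 RIP, 5049 higher and 4584 lower in ELAVL1 RIP over total RNA and 5909 higher and 4934 lower in PABPC1 RIP over total RNA. It also gave 4300 higher and 3759 lower in T7 RIP over total RNA, 4383 higher and 4736 lower in ELAVL1 RIP over PABPC1 RIP and 2467 higher in PABPC1 RIP over both controls. It also gave 991 higher over T7 RIP with both proteins. Centring without total RNA replicate 2 gave 4091 higher and 3716 lower in ELAVL1 RIP over total RNA, 6458 higher and 4162 lower in PABPC1 RIP over total RNA and 3486 higher and 2378 lower in T7 RIP over total RNA. That setting also gave 3584 higher in PABPC1 RIP over both controls. The filter at the 75th percentile gave 6220 higher in PABPC1 RIP over T7 RIP, 7159 higher in ELAVL1 RIP over total RNA and 9304 higher in PABPC1 RIP over total RNA. The filter also gave 8625 higher in T7 RIP over total RNA, 6605 lower in ELAVL1 RIP over PABPC1 RIP and 5789 higher in PABPC1 RIP over both controls. With the date batch as a random block (correlation 0.398) limma gave 1825 higher and 2673 lower in ELAVL1 RIP over T7 RIP, 887 lower in PABPC1 RIP over T7 RIP and 617 lower in ELAVL1 RIP over total RNA. The date block also gave 396 lower in PABPC1 RIP over total RNA, 1501 higher in ELAVL1 RIP over both controls and 1037 higher over T7 RIP with both proteins. A fixed term for the date gave 9592 higher and 797 lower in T7 RIP over total RNA, but T7 RIP replicates 2 and 3 are each alone on their date, so this count rests on T7 RIP replicate 1, assumed to vary like the other arrays, and does not test the date.

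The replicate block, a paired fit on the replicate number, gave 3453 higher and 5154 lower in ELAVL1 RIP over T7 RIP, and 15324 and 685 in PABPC1 RIP over total RNA. It left each of the 15 counts within 1.5 times, changed no list call in those 2 comparisons, and elsewhere added 3 list calls and ended 3.

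With each array left out in turn, the counts ranged as follows. There were 2645 to 3402 higher and 3864 to 5558 lower in ELAVL1 RIP over T7 RIP, 8422 to 9385 higher and 1127 to 1619 lower in PABPC1 RIP over T7 RIP. Total RNA comparisons had 10541 to 11207 higher and 837 to 1284 lower in ELAVL1 RIP over total RNA, 14564 to 15442 higher and 526 to 691 lower in PABPC1 RIP over total RNA, with 12347 to 13513 higher and 616 to 978 lower in T7 RIP over total RNA. The rest had 1414 to 1495 higher and 9325 to 9702 lower in ELAVL1 RIP over PABPC1 RIP, 2288 to 3117 higher in ELAVL1 RIP over both controls, 7894 to 9592 higher in PABPC1 RIP over both controls and 1755 to 2304 higher over T7 RIP with both proteins.

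Genes higher than total RNA as deposited turned negative where the shift of the medians was removed. After centring these were CORO1A at -0.90, GATA1 at -0.52, PABPC1 at -0.26 and PLG at -0.51 in PABPC1 RIP over total RNA, FGB at -0.20 and GATA1 at -0.21 in ELAVL1 RIP over total RNA, MALAT1 at -0.28 in T7 RIP over total RNA. After centring without total RNA replicate 2 these were CORO1A at -0.07, FGB at -0.45 and PABPC1 at -0.19 in ELAVL1 RIP over total RNA, CORO1A at -1.28, GATA1 at -0.27, PABPC1 at -0.55 and PLG at -1.07 in PABPC1 RIP over total RNA, MALAT1 at -0.29 and PABPC1 at -0.02 in T7 RIP over total RNA. After quantile normalization these were CORO1A at -0.37, GATA1 at -0.41 and PLG at -0.30 in PABPC1 RIP over total RNA, ELAVL1 at -0.06, LCK at -0.14 and MALAT1 at -0.48 in T7 RIP over total RNA, FGB at -0.41 and GATA1 at -0.27 in ELAVL1 RIP over total RNA. Each had an adjusted p above 0.05 in limma, except PLG (0.0418) and CORO1A (0.0114) in PABPC1 RIP without total RNA replicate 2.

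The test fry does not compare a list with other genes, so by construction the shift of the medians enters its direction, and for 36 pairs of a list and a comparison fry and camera pointed opposite ways with at least 1 of these tests passing. In PABPC1 RIP over T7 RIP the medians as deposited were AU-rich mRNAs 0.872, RNA-binding proteins 0.426, ZNF genes 0.812, cholesterol synthesis 0.488, ribosomal proteins 0.898, long noncoding RNAs -0.234 and translation factors 0.618. In ELAVL1 RIP over PABPC1 RIP the deposited medians were ELAVL1 target mRNAs -0.761, RNA-binding proteins -0.663, ZNF genes -0.799, long noncoding RNAs -1.29 and translation factors -1.24. In PABPC1 RIP over total RNA the deposited medians were RNA-binding proteins 2.72, ZNF genes 2.83, ribosomal proteins 2.44, erythroid markers 1.67, long noncoding RNAs 0.752, lymphoid markers 0.443, histones 1.53, small nucleolar and related RNAs 0.865 and translation factors 2.06. In ELAVL1 RIP over total RNA the deposited medians were cell cycle genes 1.37, cholesterol synthesis 1.15, ribosomal proteins 0.51, oxidative phosphorylation 0.691, proteasome subunits 0.548, histones 0.351, small nucleolar and related RNAs 0.798 and translation factors 0.744. In T7 RIP over total RNA the deposited medians were ribosomal proteins 1.52, erythroid markers -0.28, liver secreted proteins 1.62, long noncoding RNAs 0.888, histones 1.07, small nucleolar and related RNAs 1.33 and translation factors 1.85. The long noncoding RNAs in PABPC1 RIP over T7 RIP and the erythroid markers in T7 RIP over total RNA were the 2 pairs whose deposited median lay on the side of camera. Leaving out T7 RIP replicate 1 turned the small nucleolar and related RNAs in ELAVL1 RIP over T7 RIP to 0.68, and without each array in turn their median lay between -0.444 and 0.68. With the correlation estimated per list, 41 camera calls were lost.

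Counting any overlap of 1 base, the region lists recorded under total RNA and ELAVL1 RIP shared 363, total RNA and PABPC1 RIP shared 178. With only the regions of higher signal in each list, those recorded under ELAVL1 RIP and PABPC1 RIP shared 364, T7 RIP and ELAVL1 RIP shared 958, T7 RIP and PABPC1 RIP shared 566, total RNA and ELAVL1 RIP shared 14, total RNA and PABPC1 RIP shared 1, total RNA and T7 RIP shared 598.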

Other observations

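The tests of scaling, of the secreted class as the whole cause, of array date and of the region list records, and the 5 gene lists used here, were chosen after the results were seen.

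Homeobox genes, which encode developmental transcription factors, were tested as a further list because CDX2, NKX6-2 and GBX2 were among the largest rises with ELAVL1. These 3 genes were left out of the list, and none of them passed in ELAVL1 RIP over total RNA (GBX2 at -0.80). In ELAVL1 RIP over T7 RIP 13 of 67 rose and 1 fell, at a median of 0.42, and the list did not pass camera in limma (adjusted p = 0.0731). Against total RNA the same list fell in each RIP, with medians of -0.90 for ELAVL1, -1.66 for PABPC1 and -1.41 for T7 RIP (adjusted p = 0.000711, 6.63e-07 and 3.95e-08). As deposited its median levels were higher in the RIPs, at 8.37, 9.15 and 8.06 against 7.78 in total RNA, so this fall is relative to the array medians only. These were adjusted p = 0.740, 0.421 and 0.345 with an estimated correlation. Of 2 pluripotency markers tested, SOX2 changed by -2.72 and ZFP42 by 2.10 in ELAVL1 RIP over T7 RIP, and by -3.61 and -1.30 on the arrays labelled PABPC1 RIP.

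Total RNA replicate 2 stood apart from the other total RNA arrays. Its Spearman correlation with them was 0.830 and 0.770, against 0.934 between those. The SD of its difference from their mean was 0.937, against 0.558 between them, and small nucleolar and related RNAs were 1.20 higher on it, liver secreted proteins at -0.67 and cholesterol synthesis genes at -0.81.

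T7 RIP replicate 1, which shares the date of total RNA, also stood apart. Its Spearman correlation with the other T7 RIP arrays was 0.858 and 0.862, against 0.938 between those, and 4.8% of its values lay within 0.5 of the floor, against 1.5% and 1.9%. The SD of its difference from their mean was 1.15, against 0.642 between them. Small nucleolar and related RNAs were 2.53 higher on it, histones 1.95, cell cycle genes 1.47, oxidative phosphorylation genes 1.11, proteasome subunits 1.07 and liver secreted proteins 1.03. Without it the medians in ELAVL1 RIP over T7 RIP were -1.31 for proteasome subunits and -0.80 for oxidative phosphorylation (camera adjusted p = 5.42e-05 and 0.000922).

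Liver mRNAs were low on the arrays labelled PABPC1 RIP. A difference in scaling is argued against by the liver secreted median of -5.13 (bootstrap interval over genes -6.36 to -4.35) that was left after quantile normalization. RNA of another, non-hepatic cell line may be on these arrays, and 15 liver-specific intracellular genes had a median of -2.18 (-3.44 to -1.15), with PROX1 at -5.08, while 13 genes of non-hepatic epithelial lines had a median of 2.21 (0.85 to 3.21), with KRT7 at 3.47. Of those 13 genes 9 also lay above the array median in total RNA. Both intervals cross the bounds set beforehand for RNA of another line (-2 and 2). They lie past those set for its absence (-1 and 0.5), so neither test decides. Both lists did move the way such RNA predicts. Of the 15 genes 0 rose and 11 fell, and of the 13 genes 9 rose and 1 fell. ALB, AFP, APOA2, SERPINA1 and FOXA2 lay below the array median on each of these arrays and above it on all others. CGA, ANXA1 and SLPI, below the median on each total RNA array, read 12.38 to 13.86 here. Several of these genes were among the largest changes, so they show the pattern and do not test its cause. A PABPC1 association that differs for mRNAs of secreted and membrane proteins is argued against as the whole cause, since 28 widely expressed genes of that class had a median of -0.21 (-0.86 to 0.32), which lay 5.50 (4.35 to 6.81) above that of the liver secreted proteins, and a smaller difference for the class stays open because the interval crosses its bound of -0.5.

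Proteasome and oxidative phosphorylation mRNAs were low in ELAVL1 RIP over T7 RIP, with a median of -1.37 over 118 members (that of all genes not subtracted). Compression of high signals is argued against by random lists matched on T7 RIP level, whose median was -0.62, so that the members lay -0.74 from it and 0 of 10000 lists reached them. In the direct comparison of ELAVL1 and PABPC1 arrays on 1 date the members had a median of -2.04 (-2.38 to -1.80). This interval lay past the bound for the absence of a shared date effect, a bound written after the values were seen. A date effect shared by both groups would cancel in that comparison, and liver genes also differ there, so it cannot decide on date. A low association of proteasome and oxidative phosphorylation mRNAs with ELAVL1 remains a hypothesis, found and tested on the same data. The fall was not particular to them. In ELAVL1 RIP over T7 RIP the 28 widely expressed secretory-pathway genes had a median of -1.19 relative to all genes, with 2 rising and 15 falling. Their camera adjusted p was 0.00334, and adjusted p = 0.806 with an estimated correlation.

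The records of the region lists under T7 RIP and total RNA may be exchanged. All 19329 signals of the list recorded under T7 RIP equal the total RNA mean. The clusters of the list recorded under total RNA ranked high in T7 RIP minus total RNA, with an area under the curve of 0.786, although its signals correlated with that difference only at r = 0.233. No biological explanation was tested.

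Other splits of the arrays were counted for each comparison. In the 6 comparisons of 3 against 3 the 10 splits are too few for a share under 0.05. The real splits called 8047, 10993, 12645, 15859, 13954 and 11972 transcript clusters and the highest other split called 0, with 1 of 10 splits as large in each. For the sets over both controls and the set shared by both proteins, 100 splits were drawn without regard to replicate number, and 1 of 100 was as large in each. The counts were 2823 for ELAVL1 over both controls against a highest other of 1825, 9077 for PABPC1 against 28, and 2190 for the shared set against 2109. Replicate numbers were taken to pair ELAVL1 RIP with T7 RIP and PABPC1 RIP with total RNA, where all 3 same-number correlations passed 0.1. That choice rests on the cut, since PABPC1 RIP with T7 RIP gave 0.242, 0.396 and 0.0379. Among the 47, 45 and 50 splits that part all 3 of the pairs taken, the highest others were 1825, 0 and 2109. The real split was the largest among such splits, at shares of 1 in 47, 1 in 45 and 1 in 50. Of the 99 others in the full draw 95, 97 and 96 called 0, so the shares rest on few splits that called any. The counts are those as deposited, which carry the shift of the medians between groups. No conclusion on chance is therefore drawn from these shares. The split with 1825 kept the T7 RIP arrays together under another label and that with 2109 the ELAVL1 RIP arrays.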
